A study of Mus musculus with 52 samples.

How the data were processed

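ATAC-seq, ChIP-seq and Hi-C libraries of C57BL/6 mice were analysed from the peak lists and PC1 tables the authors deposited. Of 52 samples, 47 have a peak list and 3 a PC1 table, and the 2 ChIP-seq inputs were not analysed here. DP (CD4+CD8+, negative for CD5, CD69 and TCRb), DN3a and CD4SP cells were sorted from thymus, and proB cells were cultured from bone marrow with IL-7 and stem cell factor, per the labels' protocols. For the cultured proB libraries the cell label reads DP, while title and tissue say proB and bone marrow, and the title was followed. Samples were grouped by title and genotype. Nothing in the labels says that replicates came from separate animals, so replicate checks measure only the spread between these libraries. The p-values come from tests over regions, which are not replicates, and do not measure the spread between libraries. In the R-TEn deletion and R1pro control groups 1 replicate had 0 chromosome Y peaks and the other 13 to 25, which argues against technical repeats of 1 animal there.

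The submitters' processing notes name bcl2fastq, Bowtie2 (version 1.2.7 as given there), HOMER and the build mm9, without roles, so how duplicates, the Tn5 offset or blacklisted regions were handled is not given in the sources used here. Peaks came as 1 list per library. The score column of the deposited lists is constant in 33 lists and varies in 14, those of a later deposit. This score is the authors' value and was used only to check the order of peaks within a list. File order followed it with Spearman's rho between -0.987 and -0.911 in 8 ATAC-seq, CTCF and Smc3 lists. In 6 histone lists rho was between -0.645 and -0.486. In the 33 lists with a constant score the order could not be checked, among them all R-TEn deletion, knockout and CD4SP lists. ATAC-seq peaks have a fixed width of 151 bp in early lists and 150 bp in later ones, with a few shorter, so positions are uncertain by 1 bp between them. The PC1 score in the deposited tables has a mean of 0 and an SD of 1 in each library, in bins of 50 kb. Presence or absence of a peak depends on read depth and on the caller's threshold, so a weak region of a shallow library is read as absent. Read counts were not used here, and binomial intervals cover counting error over regions only, which are not independent of their neighbours.

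Peaks of the libraries in a comparison were merged where they overlapped by at least 1 bp. Lost and gained regions, the 2 other splits of 4 libraries, and differences between wild-type groups were counted without a test. The Rag locus was placed by the regions of chromosome 2 lost in both R-TEn deletion comparisons. There were 10 of these, of which 4 lay within 65.0 kb of each other, and the locus reaches 200 kb beyond these 4 on each side. Loss inside against outside the locus was tested with a two-sided Fisher's exact test with Benjamini-Hochberg adjustment at 0.05, intervals are exact (Clopper-Pearson, 95%), and paired losses were compared with an exact McNemar test. Windows of the locus's length were ranked where they held at least 10 control regions. For PC1, the locus mean was ranked among all runs of as many consecutive bins. Positions are 1-based. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

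The procedure was tested on simulated lists made from the 72787 peaks of a DP control library, for the comparison of the R-TEn deletion in DP cells. All 200 regions removed and all 200 added were recovered, and a run of 20 removed regions was found lost in full. These regions were exempt from the random drop of peaks, so their recovery checks the code and not its sensitivity. Dropping 2% of the other peaks at random from each list gave 16 false losses and 37 false gains, against 27.8 by calculation. The real lists differ far more, since the other splits of the same 4 libraries gave 2895 and 2860 changed regions.

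The rule fixed for named genes took Rag1, Rag2 and every lost or gained region of their locus, then genes with the most lost or gained regions and members of fixed gene lists. No mm9 genome or annotation was used here, so genes were named only from the labels and from the gene order of GRCm38.p6, regions were not assigned to exons or introns, and the gene lists and the E-box content of lost regions were not analysed. The state of Tcf3 and Tcf12 themselves was not checked for the same reason. Alternatives were another overlap rule, each library left out, the replicate number as a block, 100 and 500 kb to each side of the locus and other PC1 settings, chosen before the data were examined. Lists of equal length (each list cut, in file order, to the shortest of its comparison), the locus without its placing regions or the peak-free stretch of the deletion, the genome without the Rag locus, the R-TEn deletion comparisons without chromosome 1, and lists of equal length and each library left out for differences outside the locus were added after seeing the data.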

Results

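Open chromatin, histone marks, CTCF and cohesin were profiled in mouse lymphocytes carrying mutations in the regulatory region of Rag1 and Rag2, the genes for the recombinase that assembles antigen receptor genes. ATAC-seq, which cuts accessible DNA with the Tn5 transposase, gave 27 peak lists in 13 groups, and ChIP-seq gave 20 lists in 10 groups. Hi-C gave PC1, the first principal component of the contact map, for 3 libraries in 3 groups. The cells were CD4+CD8+ double-positive (DP) thymocytes, their earlier DN3a precursors, the later CD4 single-positive (CD4SP) thymocytes, and proB cells grown from bone marrow. The mutations were a deletion of the Rag T-cell enhancer (R-TEn), a change of the E-boxes in its element p1 (R-TEn-p1), a change of the E-boxes at the Rag1 promoter (R1pro), and a CD4Cre-driven knockout of Tcf3 and Tcf12, which encode the E proteins E2A and HEB that bind E-boxes. Each ATAC-seq and ChIP-seq mutant and control group held 2 libraries and the CD4SP ATAC-seq group held 3. The ATAC-seq lists held 40139 to 98429 peaks per library. CTCF lists held 15232 to 21838 peaks, Smc3 (cohesin) 11754 to 17620, H3K4me1 42528 to 52074, H3K27me3 17701 to 25592 and H3K27ac 13423 to 46078. Read depth is unknown, so the length of a list was the only sign of how deeply a library was read.

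A region was called lost when every control library and no mutant library had a peak there, and gained in the reverse case. The Rag locus was taken as chromosome 2 from 101183939 to 101648910 (mm9), a span of 465 kb set by 4 neighbouring regions lost in every R-TEn deletion library of both DP and DN3a cells. In the gene order of GRCm38, Rag1 lies between Rag2 and Traf6. Loss at the locus was set against the rest of the genome with a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over 11 comparisons.

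**Figure D1:**
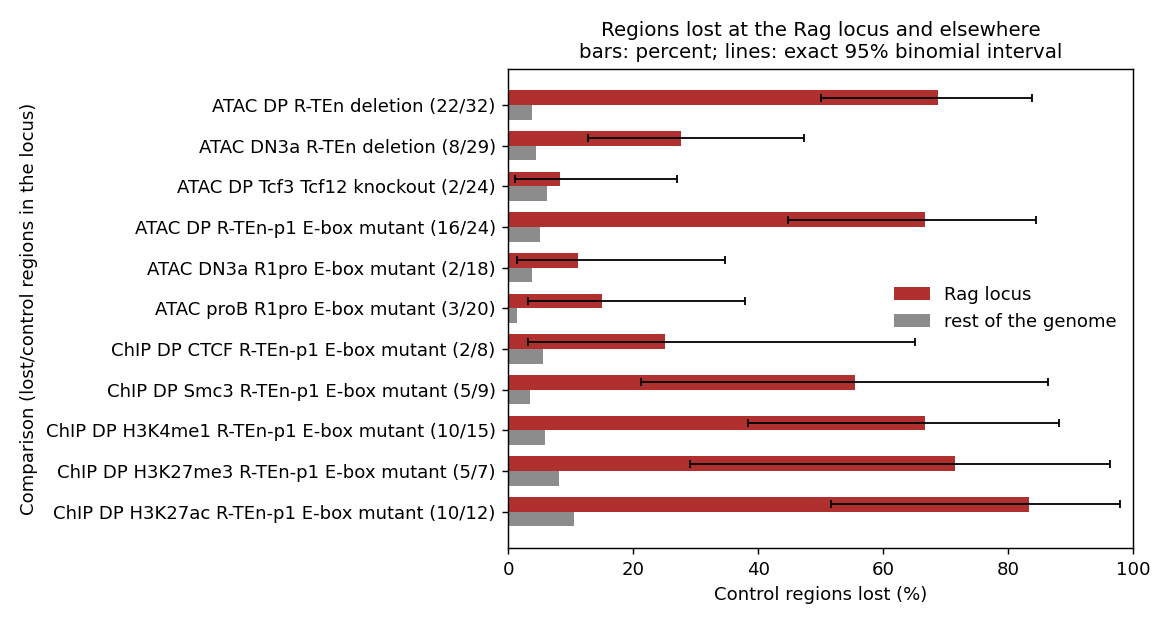
Percent of control regions lost (x axis) in each of the 11 mutant comparisons (y axis) inside the Rag locus (red, with the exact 95% binomial interval) and in the rest of the genome (grey). The locus reached 68.8% in DP cells with the R-TEn deletion and 83.3% for H3K27ac in the R-TEn-p1 mutant, against 8.33% in the Tcf3 Tcf12 knockout.

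Deletion of R-TEn was compared with wild type in DP cells to see how far accessibility depends on this enhancer. In DP cells 22 of the 32 control regions of the locus were lost, 68.8% (exact 95% interval 50 to 83.9), against 3.81% of 59114 regions elsewhere (adjusted p = 3.36e-23, Fisher's exact test). All 8 control regions between 101366175 and 101421537 were absent. This 55.4 kb stretch held no peak in any of the 4 deletion libraries of DP and DN3a cells, against 8 to 10 peaks in each control library. Its ends are peaks still called with the deletion in DN3a cells, and the labels do not give the limits of the deletion. Another 14 of the 24 control regions of the locus outside that stretch were also lost, out to 101313629 on one side and 101595392 on the other. Regions at 101505553 to 101505725, 101518469 to 101518628 and 101555907 to 101556070 were kept. Regions at 101469145 to 101469302 and 101493117 to 101493275 were gained. No other window of the same size had as large a share lost among the 2173 windows with at least 10 control regions; the next reached 42.1%.

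The same deletion removed fewer regions in DN3a cells. There 8 of 29 control regions of the locus were lost, 27.6% (12.7 to 47.2), against 4.45% elsewhere (adjusted p = 5.22e-05, Fisher's exact test), and 9 of 2839 windows, the locus included, had as large a share lost. Only 2 of the 8 lay outside the peak-free stretch, at 101432443 to 101432597 and 101448772 to 101448923, while regions at 101421538, 101438998, 101440682, 101456172, 101464766 and 101477342 were kept. Of 20 locus regions with a peak in all 4 control libraries, 11 were lost in DP and 4 in DN3a cells; 7 were lost in DP only and 0 in DN3a only (exact McNemar p = 0.0156). Deletion replicate 1 held 0 peaks on chromosome Y in both cell types, and the other DP and DN3a libraries of this experiment 13 to 20. Because the deletion libraries placed the locus, its loss in these 2 comparisons is not independent evidence. The peak-free stretch adds losses that deleted DNA would give by itself. Without that stretch and the placing regions, an alternative chosen after the data were seen, 13 of 23 regions were lost in DP cells (56.5%, p = 6e-13) and 1 of 22 in DN3a cells (4.55%, p = 1, Fisher's exact tests adjusted over both). Keeping the placing region outside the stretch gave 14 of 24 in DP (adjusted p = 3.94e-14) and 2 of 23 in DN3a cells (8.7%, adjusted p = 0.273, Fisher's exact test). In DN3a cells 2 regions were thus lost beyond the stretch, a share not detectably above that of the rest of the genome.

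**Figure D2:**
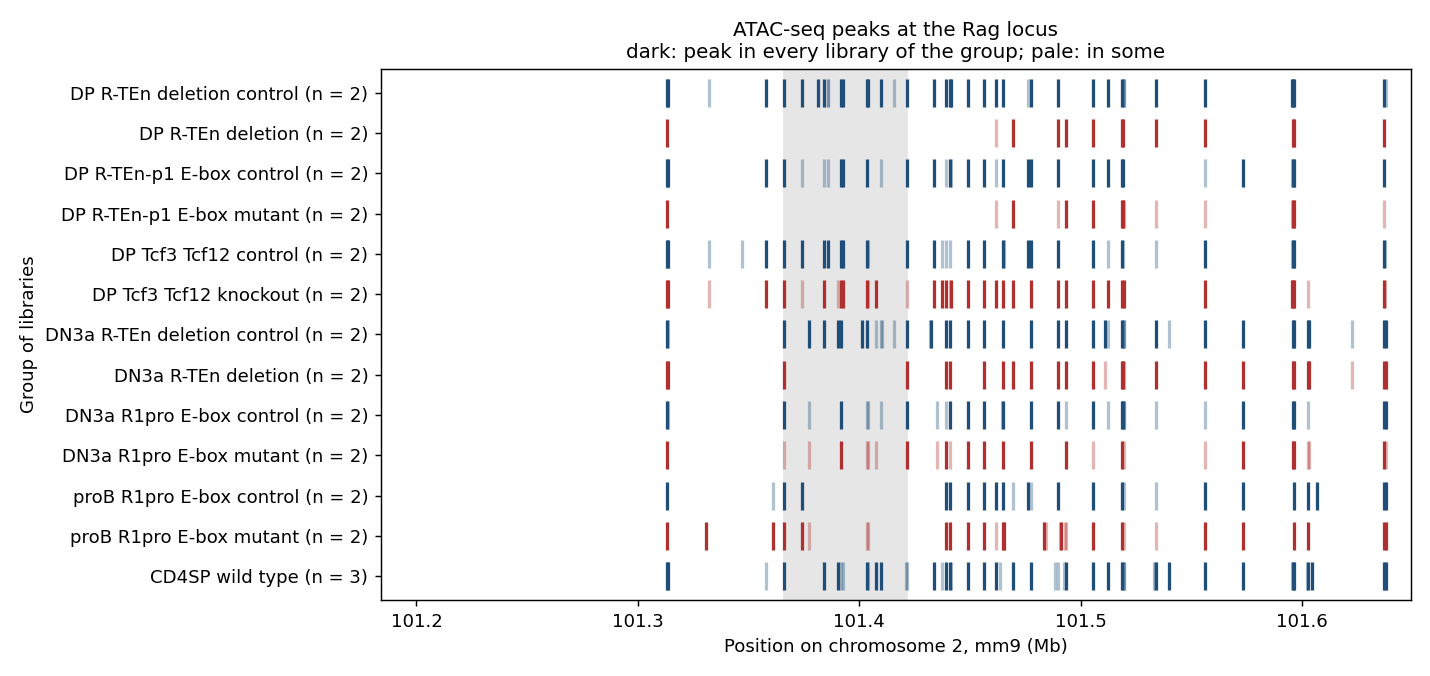
ATAC-seq peaks at the Rag locus by group (y axis, with the number of libraries) along chromosome 2 (x axis, mm9, Mb). Dark marks are peaks in every library of the group and pale marks peaks in some, blue for wild type and red for mutants, and the shaded stretch from 101366175 to 101421537 is free of peaks in all 4 R-TEn deletion libraries.

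The R-TEn-p1 E-box mutant left the rest of the enhancer in place and was compared with its own wild-type libraries in DP cells. Of 24 control regions of the locus, 16 were lost, 66.7% (44.7 to 84.4), against 5.12% elsewhere (adjusted p = 6.32e-15, Fisher's exact test). Lost regions lay at 101357782 to 101357938, 101391634 to 101391835, 101403379 to 101403569, 101448763 to 101448916 and 101477297 to 101477510, among others. Regions at 101469093 to 101469300 and 101493118 to 101493282 were gained. Over the 21 locus regions with a peak in all 4 control libraries of both experiments, 14 were lost in the deletion and 14 in the E-box mutant, and all 14 were the same regions, against 9.33 for independent lists. In the rest of the genome the 2 comparisons shared 122 lost regions, against 11.4 for independent lists, and they share no library. Other pairs also exceeded independence there: 123 against 38.4 for R-TEn-p1 and the knockout, 64 against 13.8 for the deletion in DP and DN3a cells, and 7 against 1.78 for R1pro in DN3a and proB cells. Over the whole genome the shared count was 136, and 66 with lists of equal length (4.14 for independent lists).

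Histone marks, CTCF and cohesin were compared between wild-type and R-TEn-p1 mutant DP cells. H3K27ac, a mark of active enhancers and promoters, was lost from 10 of its 12 control regions at the locus, 83.3% (51.6 to 97.9), against 10.5% elsewhere (adjusted p = 2.57e-08, Fisher's exact test). The lost H3K27ac regions included 101388636 to 101397156, 101400905 to 101405673 and 101460161 to 101468979. H3K4me1, found at enhancers, was lost from 10 of 15 regions, 66.7% (38.4 to 88.2), against 5.86% elsewhere (adjusted p = 4.13e-09, Fisher's exact test), among them 101379819 to 101397428 and 101469364 to 101487035. H3K4me1 regions at 101437169 to 101442691, 101454495 to 101464325, 101488840 to 101493844 and 101519519 to 101522296 had peaks in both mutant libraries. H3K27me3, a mark of Polycomb repression, was lost from 5 of 7 regions, 71.4% (29.0 to 96.3), against 8.07% (adjusted p = 9.95e-05, Fisher's exact test). The 5 lay between 101300115 and 101348327, and H3K27me3 was gained at 101469331 to 101470153 and 101501903 to 101503289. By count, 5 windows of the locus's size, the locus included, lost as many H3K27me3 regions or more. Among other windows with at least 10 control regions, the highest share lost was 61.5% (8 of 13).

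Smc3, a cohesin subunit, was lost from 5 of 9 control regions of the locus, 55.6% (21.2 to 86.3), against 3.54% elsewhere (adjusted p = 1.44e-05, Fisher's exact test). The Smc3 regions lost lay at 101365942, 101383855, 101391566, 101448722 and 101555825. CTCF, an insulator protein at which cohesin often stops, was lost at 101365804 to 101366415 and 101383722 to 101384333, both sites of Smc3 loss, and these were 2 of its 8 control regions, 25% (3.19 to 65.1), against 5.55% elsewhere. This share did not pass Fisher's exact test (adjusted p = 0.0846) but did with 100 kb to each side (2 of 6, adjusted p = 0.0488) and with lists of equal length (adjusted p = 0.0343), so the call at 8 regions depends on these settings. CTCF at 101312792, 101492902, 101518207 and 101555672 had peaks in both mutant libraries. Over the genome, 76.7% and 64.7% of Smc3 regions overlapped a CTCF region in the wild-type libraries, and 67.9% and 53.2% in the mutant libraries of the same numbers. The mutant was lower at both numbers. The 2 libraries of each genotype differed by more, but replicate 2 was deposited later, so that gap includes a batch difference. The difference between genotypes was not tested. The width of CTCF peaks also changed between libraries, from 287 bp (wild type) and 181 bp (mutant) in replicate 1 to 612 and 614 bp in replicate 2. In replicate 1, CTCF peaks covered 6.27 Mb in wild type and 3.01 Mb in the mutant. In replicate 2, the Smc3 list held 11754 peaks in wild type and 17620 in the mutant. Such differences between lists could lower the mutant overlap without any change in cohesin.

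**Figure D3:**
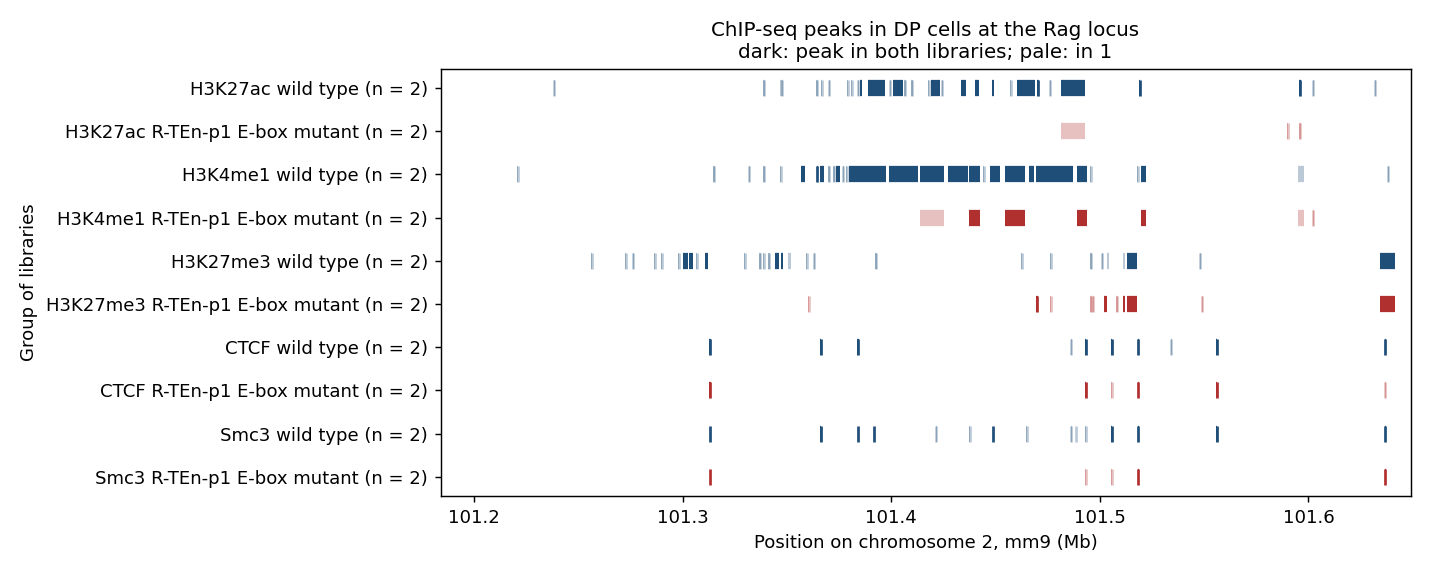
ChIP-seq regions in DP cells at the Rag locus for 5 targets, wild type in blue and R-TEn-p1 E-box mutant in red (y axis), along chromosome 2 (x axis, mm9, Mb). Dark bars are regions with a peak in both libraries and pale bars in 1; 10 of 12 H3K27ac and 10 of 15 H3K4me1 regions of the wild type have no mutant bar.

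The E-boxes at the Rag1 promoter were changed in DN3a and in cultured proB cells. In both, the region around 101489683 to 101489847 was lost, with peaks in both control libraries and neither mutant library of each cell type. The nearest of the 4 regions that placed the locus lies at -40.9 kb from it. In DN3a cells 101519040 to 101519201 was the only other region of the locus lost, and 2 of 18 regions, 11.1%, were lost against 3.83% elsewhere (adjusted p = 0.165, Fisher's exact test). Without control replicate 1 the DN3a locus lost 8 of 32 regions, 25%, below the 26.2% elsewhere, and without mutant replicate 2 it lost 6 of 18, 33.3%, against 26.2%. In proB cells 3 of 20 were lost, 15%, against 1.41% elsewhere (adjusted p = 0.0037, Fisher's exact test), the others at 101476065 to 101476276 and 101606803 to 101606989. Peaks appeared at 101483490 and 101491097 on either side of the promoter region in both proB mutant libraries. The proB call, by Fisher's exact test, was not met with lists of equal length (2 of 17, adjusted p = 0.107), without control replicate 1 (3 of 22, adjusted p = 0.532), without mutant replicate 1 (3 of 20, adjusted p = 0.0665) and without mutant replicate 2 (4 of 20, adjusted p = 0.14), and was met without control replicate 2 (5 of 23, adjusted p = 0.00821) and at 100 and 500 kb to each side (adjusted p = 0.0193 and 0.0211). Both R1pro mutant libraries of both cell types held 0 peaks on chromosome Y, as did control replicate 1 of each, while control replicate 2 held 23 in DN3a and 25 in proB cells.

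Loss of Tcf3 and Tcf12 in DP cells left most of the locus accessible. Of 24 control regions 2 were lost, at 101385861 to 101386016 and 101476059 to 101476225, which is 8.33% (1.03 to 27) against 6.26% elsewhere (adjusted p = 0.66, Fisher's exact test). The share was 18.2% (6 of 33) without control replicate 2, against 11.5% elsewhere, 12.5% (3 of 24) without either knockout replicate and 16.7% (4 of 24) with lists of equal length, and none of these passed Fisher's exact test (adjusted p = 0.292, 0.73, 0.731 and 0.128). The knockout gained 6 regions there, including 101469096 to 101469252 and 101493119 to 101493270. Over 20 locus regions with a peak in the control libraries of both experiments, 13 were lost in the R-TEn-p1 E-box mutant and 1 in the knockout. Of these, 12 were lost in the E-box mutant only and 0 in the knockout only (exact McNemar p = 0.000488). E-box mutant lists were shorter than their controls (55093 and 46753 against 59960 and 53699 peaks). Knockout lists were longer (65606 and 59836 against 56842 and 55456), which tilts this test toward losses in the E-box mutant. It was not run with lists of equal length, where the separate shares were 57.9% in the E-box mutant and 16.7% in the knockout. Whether Tcf3 and Tcf12 protein was gone from the sorted cells is not measured by these lists.

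Genome-wide, the Tcf3 Tcf12 knockout lost 3006 of 47984 regions and gained 5569, 8575 in all, against 2338 and 1920 for the other splits of the same 4 libraries. The R-TEn deletion changed 3545 regions in DP cells (2277 lost, 1268 gained; other splits 2895 and 2860) and 6095 in DN3a cells (3703 lost, 2392 gained; 4347 and 3960). The R-TEn-p1 mutant changed 3146 ATAC-seq regions, below 4050 for the split by replicate number and above 2074 for the crossed split. For R1pro and ChIP-seq, replicate 2 was deposited later with other peak widths, so the split by replicate number is a batch split, while the crossed split balances the batch as the real split does. R1pro changed 2144 regions in DN3a and 2849 in proB cells, against 21200 and 10530 by batch and 1385 and 2008 crossed. In ChIP-seq the real split gave 925 CTCF regions, 1183 Smc3, 3606 H3K4me1, 1726 H3K27me3 and 1475 H3K27ac. The batch split exceeded it in each (2761, 2433, 5299, 3088 and 7187), and the crossed split was larger for CTCF (1049) and smaller for the others (1157, 3316, 1553 and 1168). With 2 libraries against 2, an exact test over the splits cannot go below p = 0.333.

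Wild-type DP libraries of different experiments differed from each other at 3323 to 9940 regions, and at 3218 to 7457 with lists of equal length. The knockout changed 7571 regions with lists of equal length, the DP deletion 3359 and the R-TEn-p1 mutant 2371. Wild-type DN3a sets differed at 9821 regions and at 4309 with lists of equal length, where the DN3a deletion changed 5871. Each comparison had its own common length, 47150 peaks for the wild-type DN3a sets and 93185 for the DN3a deletion. For DP cells it was 55456 for the knockout, 64540 for the deletion, 46753 for R-TEn-p1 and 53699 or 55456 between wild-type sets. Counts at unlike lengths are not on the same scale, so 5871 over 4309 does not place the DN3a deletion above the wild-type background. The genome-wide direction of these changes was not read, since unequal list lengths can tilt it and a common length limits how far losses and gains can differ. The lost share of changes went from 35.1% to 51.3% for the knockout, from 77.3% to 50.7% for R-TEn-p1, and from 77.0% to 50.7% and 22.5% to 47.6% for R1pro in DN3a and proB cells. It went from 64.2% to 52.4% and 60.8% to 50.6% for the deletion in DP and DN3a cells. In ChIP-seq it went from 81.4% to 52.0% for CTCF, 26.0% to 51.6% for Smc3 and 67.6% to 45.9% for H3K27ac, and away from balance from 51.9% to 44.9% for H3K4me1 and 52.4% to 38.4% for H3K27me3. At the Rag locus wild-type DP libraries of different experiments lost 0 to 12.5% of regions, which never exceeded their rest of the genome (p = 1 in each of 3 Fisher's exact tests). The wild-type DN3a sets differed at 20.7% of locus regions against 11.3% of the genome (p = 0.133, Fisher's exact test).

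Wild-type cell types differed more than any mutant from its control. From DN3a to DP cells 28163 of 82983 regions were absent and 7195 were new. From DP to CD4SP cells 6277 of 59156 were absent and 15356 were new, and proB cells lacked 13030 of 43053 DN3a regions and had 11650 others. With lists of equal length the absent regions were 51.7% of the DN3a to DP changes in place of 79.7%, and 48.2% in place of 29.0% for DP to CD4SP. At the Rag locus DN3a and DP cells shared 20 regions, 8 were in DN3a only and 9 in DP only. DP regions absent from DN3a included 101357789, 101392676 and 101433734, all lost again in both R-TEn mutants. DN3a regions absent from DP included 101377082, 101390491 and 101401080, inside the stretch left peak-free by the deletion. In the other wild-type DN3a set, the R1pro control, these had peaks in 1, 0 and 0 of 2 libraries. The region at 101390491 also had peaks in all 3 CD4SP libraries. ProB cells had none of the regions from 101383930 to 101421814 in their control libraries, but shared 13 locus regions with DN3a cells. CD4SP cells had 21 of the 32 DP regions in every library, lacked 3 and had 8 others, among them 101469093 to 101469302 and 101493110 to 101493282.

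Hi-C PC1 fell across the left part of the Rag locus in DP cells without R-TEn. PC1 is positive here where ATAC-seq peaks are dense (Spearman's rho 0.782 over autosomal bins of the DP control). Over the 10 bins of 50 kb in the locus its mean was 0.725 in the control and 0.157 in the deletion, a change of -0.568. The 5 bins of the genome with the largest falls were all neighbours on chromosome 2: 101150001 to 101400000, where PC1 changed by -0.902, -1.04, -1.22, -1.10 and -0.906. At 101250001 to 101300000 it went from 0.559 to -0.658. The bin at 101500001 had 1.06 in the control and 1.08 in the deletion, and 7 of the 10 locus bins were lower in the deletion. Of 49506 windows of the same length 8 had a mean change as low, and all 8 overlap the locus. In CD4SP cells the locus mean was 0.299, a change of -0.426 from DP cells, lower in 10 of 10 bins and at percentile 1.01 of its windows. Both changes subtract the same DP control library, so their common direction is not independent evidence. PC1 in CD4SP cells was -0.279 at 101250001 to 101300000. Over the genome 643 of 50485 bins (1.27%) changed sign with the deletion, 232 to negative and 411 to positive, 3 of them among the 10 locus bins, and 1700 of 50731 (3.35%) between DP and CD4SP, 465 of these on X and Y, with the 10 largest falls and the 10 largest rises all on X. Each group was 1 library, so no difference has a replicate check, and CD4SP cells were prepared with another protocol (tethered conformation capture) than DP cells, so protocol and cell type cannot be told apart.

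**Figure D4:**
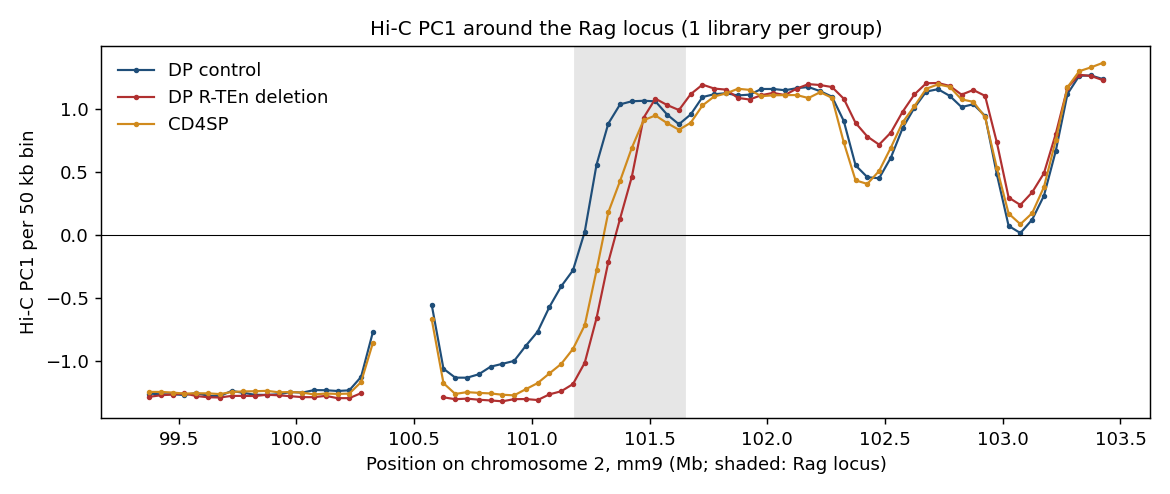
Hi-C PC1 per 50 kb bin (y axis) along chromosome 2 around the Rag locus (x axis, mm9, Mb, locus shaded) in DP control (blue), DP R-TEn deletion (red) and CD4SP (orange), 1 library each. The boundary from negative to positive PC1 lies further right in the deletion and in CD4SP cells than in the DP control, and gaps are bins with no value.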

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

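The test on other wild-type DP libraries was chosen after the result was seen, as were the alternatives for regions outside the locus, and lists of equal length at the locus after the data were seen but before this result. The R-TEn deletion differed between cell types at the Rag locus, with 7 regions between 101366017 and 101477536 lost in DP only and 0 in DN3a cells only (exact McNemar p = 0.0156). Lists of different length are argued against if file order ranks peaks, which could not be checked in these lists because their score is constant. With all 8 lists of equal length 6 were lost in DP only and 0 in DN3a only (exact McNemar p = 0.0312). Of the 16 shared regions not lost in DN3a cells, 7 were missing from both DP deletion libraries. Of the same 16 regions, 1 was missing from both wild-type DP libraries of the R-TEn-p1 experiment and 0 from those of the knockout experiment. Fisher's exact test gave p = 0.001004 for 7 of 16 against 1 of 32 cases. That test counts the same regions once per wild-type set and ignores their pairing, so its p is too small. Chance misses of weak peaks are therefore less likely but not excluded. The cell type stays open, and a wider dependence of the locus on R-TEn in DP than in DN3a cells is a hypothesis consistent with these tests.

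Outside the locus, losses in the R-TEn deletion also differed between cell types, with 1113 regions lost in DP only and 495 in DN3a only (exact McNemar p = 9.16e-55). Losses in the R1pro mutant differed likewise, with 372 regions in DN3a only and 109 in proB cells only (exact McNemar p = 1.21e-34). With lists of equal length the numbers for the R-TEn deletion were 557 and 528 (exact p = 0.395), so that difference did not hold, and its direction turned without either DN3a deletion replicate. Those for R1pro were 322 and 181 (exact p = 3.33e-10), but the direction turned without either proB mutant replicate or without proB control replicate 1.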

How the results depend on the processing

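Lists of equal length, the locus without its placing regions or the peak-free stretch, the genome without the Rag locus, the counts without chromosome 1 and all alternatives for differences outside the locus were chosen after seeing the data. Loss at the Rag locus kept its direction and side of the threshold in 74 of 83 alternatives, and the 9 others concern CTCF, the R1pro mutant and the R-TEn deletion in DN3a cells. The last no longer passed without the peak-free stretch (8.7%), nor without it and the placing regions (4.55%), as the lost regions left out lie mostly in that stretch. In DN3a cells R1pro, not called, turned to 25% against 26.2% elsewhere without control replicate 1, where the later, longer control list meets both mutant lists (range without each library 10.5% to 33.3%). CTCF passed the threshold at 100 kb to each side (33.3%) and with lists of equal length (25%), and the cause was not tested. The proB loss no longer passed with lists of equal length (11.8%) and without control replicate 1 or either mutant replicate. Its range without each library was 13.6% to 21.7%, and the cause was not tested.

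Of 98 alternatives for counts of lost or gained regions, 52 stayed within 1.5 times the main count. Leaving out 1 library raises these counts by construction, since fewer libraries have to match. The ranges were 8960 to 11256 (R-TEn deletion, DP), 14891 to 15788 (DN3a), 13887 to 18824 (Tcf3 Tcf12 knockout), 7831 to 10457 (R-TEn-p1, ATAC-seq), 8677 to 24978 (R1pro, DN3a) and 8764 to 18090 (proB). For ChIP-seq they were 2966 to 4683 (CTCF), 3666 to 6514 (Smc3), 12027 to 14228 (H3K4me1), 6366 to 9876 (H3K27me3) and 5002 to 30245 (H3K27ac). Between wild-type proB and DN3a cells the range was 32265 to 57166, the highest without DN3a control replicate 1. H3K27ac gave 878 with lists of equal length, and the cause was not tested. The other alternatives with more than a 1.5-fold change were all leave-one-out counts.

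With replicate number as a replicate block, all 11 counts stayed within 1.5 times, such as 3600 for the R-TEn deletion in DP cells and 8617 for the knockout. Deviations of same-numbered libraries correlated over 0.1 in 4 of 11 comparisons, with only 2 pairs each, so no paired test was used.

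Of regions outside the locus lost in 1 cell type only, 69.2% were lost in DP for the R-TEn deletion and 77.3% in DN3a for R1pro. The first became 51.3% with lists of equal length, 40.9% and 44.0% without DN3a deletion replicate 1 or 2, and 40.9% to 84.8% over all libraries. The second became 38.9%, 24.3% and 49% without proB mutant replicate 1, mutant replicate 2 or control replicate 1, and 24.3% to 98.1% over all libraries. Leaving out a library of 1 cell type raises the losses of that type by construction, and for lists of equal length the cause was not tested.

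Regions lost in both the R-TEn deletion and the R-TEn-p1 mutant numbered 66 with lists of equal length, and 180 to 428 without each library in turn, the latter again by construction. PC1 at the locus changed by -0.655 with 100 kb and -0.386 with 500 kb to each side in the deletion, and by -0.464 and -0.306 in CD4SP cells, as the bins averaged differ. Gene lists and E-box motifs were not run for want of a genome annotation. Peak lists limit all counts to presence or absence, so a fall in signal that leaves a peak called is not seen.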

Other observations

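The tests by chromatin mark, for a carried strain segment, of chromosome 1 between mutants, and for list length and CD4SP cells in the knockout were chosen after the result was seen, and the last 2 replaced earlier forms that could not decide. For chromosome 1, lists of equal length were chosen after the data were seen but before that result. Regions that DP cells lost with Tcf3 and Tcf12 carried enhancer marks in wild-type DP cells more often than regions kept. H3K4me1 covered 65.9% of 3006 lost regions against 37.9% of 41261 kept regions (adjusted p = 1.78e-195), and H3K27ac 29.9% against 20.2% (adjusted p = 1.33e-33, Fisher's exact tests over 30 comparisons). CTCF lay at 3.99% of lost, 5.35% of gained and 24.8% of kept regions, and was likewise rarer at changed regions in the R-TEn deletion in DP cells (7.51%, 3.47% and 21.6%) and the R-TEn-p1 mutant (11.3%, 10.6% and 23.2%). Regions gained in the knockout had H3K27ac less often than kept ones, 8.48%. Gained regions by definition lack an ATAC-seq peak in the wild-type control libraries. Their lower shares of H3K27ac and CTCF, both measured in wild-type DP cells, are therefore partly built in. In the R-TEn deletion, lost regions had H3K4me1 at 31.9% and kept regions at 41.7% (adjusted p = 7.82e-21, Fisher's exact test), the other direction from the knockout. The R-TEn deletion changed 3545 regions in DP cells, against 2895 and 2860 for the other splits of its libraries. The R-TEn-p1 mutant changed 3146, against 4050 by replicate number and 2074 crossed. Regions changed in the other splits were not tested for marks, so the shares in these mutants are not assigned to the mutations. Kept regions had a peak in every library of a comparison and changed regions in 1 genotype only, and peak strength was not compared.

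Regions changed by the knockout were often those that differ between DP and CD4SP cells, in libraries the knockout comparison does not use. Of regions lost in the knockout 42.2% were also absent from CD4SP cells, against 2.30% of kept regions, while for the R-TEn-p1 mutant these were 9.17% and 5.38%. Of gained regions 28.0% in the knockout and 7.27% in the R-TEn-p1 mutant were also new in CD4SP cells, against 1.32% and 0.477% of kept regions, a base that is low in both because kept regions have DP peaks. Relative to another wild-type DP set this was 39.4% for the knockout, against 20.6% of regions that differ only between wild-type sets (odds ratio 2.51, Fisher's exact p = 3.66e-126). Longer knockout and CD4SP lists, which would add shared gains, are argued against if file order ranks peaks, unchecked in these lists. With lists of equal length the percentages were 32.8% for the knockout and 9.41% between wild-type sets (odds ratio 4.69, Fisher's exact p = 4.43e-137). A state closer to CD4SP cells and CD4SP cells in the sort, which the gate against TCRb should remove, cannot be told apart. With lists of equal length 10.5% of regions gained in CD4SP were gained in the knockout and 19.7% of those lost were lost, but losses also outweighed gains in the R-TEn-p1 mutant (1.88% and 0.476%).

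Regions changed in the R-TEn deletion in both DP and DN3a cells lay on chromosome 1 in 40 of 107 cases, 37.4% (exact 95% interval 28.2 to 47.3), against 6.47% of regions kept in both, with 24 of 68 lost and 16 of 39 gained regions there. List length is argued against if file order ranks peaks, unchecked in these lists, since with lists of equal length 33.0% lay there (24.3 to 42.7). A variable part of chromosome 1 is argued against as well: between 120 and 170 Mb the percent of regions changed was at most 1.12 times that elsewhere in the other 4 ATAC-seq comparisons, against 2.14 and 1.69 in the deletion. Regions changed in 1 cell type only were also more frequent between 130 and 170 Mb. The odds ratio was 1.53 in DN3a and 1.81 in DP cells (Fisher's exact p = 8.05e-07 and 2.45e-08). This stretch was chosen after these libraries were seen, and any local difference between deletion and control libraries there would give such an excess. A segment of another strain therefore cannot be told apart from other causes, and the Rag locus itself lies on chromosome 2. No genotypes were used here and no biological explanation was tested.

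In a stretch picked after its values were seen, between 54 and 54.5 Mb of chromosome 14, 14 of 60 regions were lost in the Tcf3 Tcf12 knockout and 12 of 52 in the R-TEn-p1 mutant, 2 of them the same. In the R-TEn deletion 5 of 64 were lost there in DP and 1 of 44 in DN3a cells, and in the R1pro mutant 0 of 14 in DN3a cells. The locus region at 101469093 to 101469302 was called in both libraries of the DP and DN3a R-TEn deletion, the R-TEn-p1 mutant and the Tcf3 Tcf12 knockout and in all 3 CD4SP libraries, in none of the wild-type DP or DN3a libraries, and in 1 of 2 proB control libraries.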
